A study of Rattus norvegicus with 4 samples.

How the data were processed

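Gene expression was measured in whole retinas of albino Lewis rats on 4 two-colour arrays. Per the labels' protocols, retinas were pooled, RNA was extracted on columns, and total RNA was amplified and labelled with Cy5 and Cy3. Per the labels, 2 arrays compared 11 weeks with 5 weeks and 2 compared 20 weeks with 5 weeks, each pair with the dyes exchanged. Arrays were grouped by the older age. The scanner, the image software and any normalization are not given in the sources used here.

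The deposited values are log2 ratios of the channels of each array, judged from the values: 251 probes without a listed gene stood at log2 of 100000 on some array, always on the positive side. The scale is thus known, but the centring and direction are not stated. Array medians over all probes were -0.05, -0.03, 0.55 and -0.14 in the order of the 11-week Cy5, 20-week Cy3, 20-week Cy5 and 11-week Cy3 arrays, named by the older retina's dye. The direction was taken as Cy5 over Cy3, as likely, from the titles, which put the age labelled with Cy5 before the other. The ceiling was positive on all 4 arrays, whatever their orientation, so the ratios had not been turned to one age, which does not tell Cy5 over Cy3 from the reverse. Ratios already turned to one direction would make arrays of a pair covary more than opposite-dye arrays of different ages. They covaried less, by -0.0270 (95% bootstrap interval -0.0297 to -0.0243). Spot intensities were not used here, so no loess correction, background filter or statement on detection was made.

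Probes were named through the platform's gene table, in which 12750 of 22575 probes had 1 gene, 5 had several and 9820 had none. The gene identifiers of 12720 probes were found in the gene table of the GRCr8 assembly, which changed 0 symbols. Probes with several genes or none were left out, since 298 probes without a gene had ratios under -0.4 on all 4 arrays, against 1 named probe, a pattern that control spots would give. Values at the ceiling were set to missing. Each array was centred on its median over named probes, and the probes of a gene were averaged, giving 9653 genes (7387 with 1 probe, 2266 with more). Centring had been planned as the alternative and the ratios as deposited as the setting to report. They were exchanged before any test was run because the array medians differed. As deposited, the median gene lay at 0.06 at 11 weeks and 0.29 at 20 weeks. The restriction to named probes was also made after the values were seen.

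Each array was given the sign of its orientation, and limma 3.58.1 (lmFit and eBayes, R 4.3.3) fitted the 11-week and 20-week changes over all 4 arrays with 2 residual degrees of freedom. The difference of both changes gave 20 against 11 weeks. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and tests were two-sided. The reported model had no dye term. A model with a dye term, also fixed beforehand as a second choice, left 1 residual degree of freedom, with a prior of 8.83 degrees of freedom from the spread across genes, against 2.63 without it. It assumes that a gene's dye effect was alike on all 4 arrays.

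Both models were tested on simulated data with the measured dye effects and spread, in which a few of 9652 genes were changed. With a dye term, 62 of 68 genes changed 1.25-fold at 11 weeks were recovered, and all 66 changed 1.5-fold and all 66 changed 2-fold, with 28 unchanged genes called. At 20 weeks the counts were 61, 66 and 66, with 22 unchanged genes called. In both comparisons, unchanged genes were a larger share of the calls than the adjusted p threshold aims at. The model with a dye term thus did not hold its error rate in this simulation. Without a dye term 0 were recovered in either comparison. The simulation took dye effects as equal across arrays, so it does not bear on that assumption.

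Before the data were examined, 32 gene lists were fixed. They cover rods, cones, bipolar, amacrine and horizontal, ganglion, and Müller and astrocyte cells. Tissues that a dissection can carry were pigment epithelium and choroid, lens, blood, vessels, cornea with conjunctiva and iris, skeletal muscle and myelin. The other lists hold retinal stress, complement and antigen presentation, microglia and leukocytes, interferon response, extracellular matrix, cell cycle, neuronal development, synapse, respiration, glycolysis, ribosomal proteins, clock, immediate early, heat shock, antioxidant, apoptosis, lipid synthesis, growth and thyroid hormone, and sex-linked genes. The 31 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over lists. An estimated correlation and fry were the alternatives. With an estimated correlation, camera tests on the residual degrees of freedom, 2 or, with a dye term, 1, so a list can hardly pass. The preset takes the genes of a list as nearly independent, so its p-values rest on genes rather than arrays.

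Genes were named by a rule fixed beforehand: the 10 highest and 10 lowest passing changes, or, if no gene passed, the 10 with the largest mean change that moved one way on both arrays of each pair used. Symbols of clone type were excluded. Up to 4 members of each described list with the largest change were added, passing or not, and Gfap, Glul and Thy1 always. Opn1sw, Gapdh and Actb, also meant to be given always, had no probe among those used and were not analysed here. As no gene passed in the reported model, the second form applied.

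A comparison of the genes passing at both ages with the overlap of independent lists had been planned and is not used here, since both changes share the 5-week retina and one model.

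Alternatives planned were the dye term, centring, a common scale, single probes, leaving out genes with a missing or 0 ratio, leaving out the 50% of genes with smaller ratios, robust moderation, a 1.5-fold threshold with and without a test, and each array left out in turn. Added after seeing the data were all probes, the dye term together with each other choice, and the dye term with an estimated correlation in camera. Intervals of medians used 10000 bootstrap resamples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.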

Results

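Whole retinas of albino Lewis rats were compared at 5, 11 and 20 weeks of age, to follow gene expression as the retina matures. Pooled retinal RNA of an older age and of 5 weeks was labelled with Cy5 and Cy3 and hybridised together on 4 two-colour arrays. The 11-week retina was set against the 5-week retina on 2 arrays with the dyes exchanged, and the 20-week retina likewise on 2 others. The value table held 22575 probes, of which 12750 were listed with 1 gene, covering 9653 genes. Before centring, the median log2 ratio of all probes was -0.05 and -0.14 on the arrays with the 11-week retina in Cy5 and in Cy3, and 0.55 and -0.03 on those with the 20-week retina in Cy5 and in Cy3. The number of arrays limits the precision, and the labels do not say that the 2 arrays of a pair held separate RNA. P-values therefore measure the spread between arrays, which may be technical. If the arrays of a pair held the same RNA extracts, each comparison rests on 1 pool per age and has no test.

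Changes below are log2 ratios of the older over the 5-week retina, relative to the median gene of each array, as mean ± SD of 2 arrays. The ratios were taken as Cy5 over Cy3, the likely direction, so all signs rest on it, and with the direction turned every "higher" and "lower" is exchanged. The limma model fixed beforehand had no dye term and passed 0 genes in any comparison. A second model, also fixed beforehand, with a gene-wise dye effect common to the 4 arrays gave the same mean changes with smaller errors, and "passed" below means an adjusted p under 0.05 in that model. That model's errors rest on how far a gene's dye effect differed between the 2 pairs of arrays, and on the spread across genes. They do not rest on the SD printed beside a change, which includes the dye effect. In simulated data, unchanged genes were a larger share of that model's calls than this threshold aims at.

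At 11 weeks, the ribosomal protein, respiratory chain, rod and lens lists had medians below the median gene, at -0.37, -0.24, -0.20 and -0.18, and 35 of 47, 20 of 40, 10 of 26 and 7 of 14 genes passed as lower. These list calls were lost with an estimated correlation, with adjusted p = 0.53 with an estimated correlation for rods and 0.46 for each of the others. With 2 residual degrees of freedom that form could hardly pass any list, so the loss does not tell the lists apart. The preset p-values rest on genes taken as nearly independent, not on arrays. Cryba4, a lens beta-crystallin, had the largest change, -1.21 ± 0.0028 (SD, n = 2), with an adjusted p of 5.43e-05 in the model with a dye term. Cryaa, the alpha-A crystallin, was at -0.83 ± 0.17. Higher were Dhodh, a mitochondrial enzyme of pyrimidine synthesis, at 0.95 ± 0.21, and Kmo, an enzyme of the kynurenine pathway, at 0.95 ± 0.06. Ccl2, a monocyte chemoattractant, was at 0.83 ± 0.05, and Rpf2, a ribosome assembly factor, at 0.77 ± 0.16. Sdc1, the proteoglycan syndecan-1, was at 0.95 ± 0.67, the kidney phosphate transporter gene Slc34a1 at 0.90 ± 0.42 and the intestinal defensin gene Defa5 at 0.86 ± 0.64. Ccrl2, an atypical chemoattractant receptor, was at -0.84 ± 0.31, and at -0.50 in the model with a dye term without the array with the 11-week retina in Cy3. These 10 genes had the largest mean changes among those that moved one way on both arrays, and all 10 passed with a dye term. None passed without it.

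Among the gene lists fixed beforehand, the ribosomal proteins had the lowest median. Of 47 measured genes, 35 passed as lower, 0 as higher and 12 did not pass, with a median of -0.37. Adjusted over the list alone, 40 were lower. Rps21 was at -0.68 ± 0.31, Rps29 at -0.68 ± 0.36 and Rps13 at -0.58 ± 0.10. The set test camera gave an adjusted p of 3.35e-23 with its preset correlation, and adjusted p = 0.46 with an estimated correlation. Of 40 respiratory chain and ATP synthase genes, 20 passed as lower and 0 as higher (23 lower adjusted over the list alone), with a median of -0.24. Cox7a2 was at -0.58 ± 0.17 and Cox5b at -0.48 ± 0.03. Camera gave an adjusted p of 8.98e-12, and adjusted p = 0.46 with an estimated correlation.

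Of 26 rod phototransduction genes, 10 passed as lower and 0 as higher (13 lower adjusted over the list alone), with a median of -0.20. Gngt1, the gamma subunit of rod transducin, was at -0.64 ± 0.50, Prph2, a disc rim protein, at -0.52 ± 0.42, and Rcvrn, recoverin, at -0.45 ± 0.02. In the model with a dye term, Rcvrn was at -0.24 without the array with the 11-week retina in Cy5. For this list the adjusted p was 7.13e-05, and adjusted p = 0.53 with an estimated correlation. Of 14 lens genes, 7 passed as lower and 0 as higher, all 7 of them crystallins (adjusted over the list alone, 7 lower and 1 higher). Cryab was at -0.58 ± 0.09 and Crybb2 at -0.55 ± 0.36. The median was -0.18 and the adjusted p 4.82e-05, with adjusted p = 0.46 with an estimated correlation. Without a dye term and adjusted over the list alone, 3 lens genes passed at 11 weeks and 3 at 20 weeks.

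Shifts past the preset test were seen in 6 further lists. Each call was lost with an estimated correlation, with adjusted p = 0.59 for glycolysis and adjusted p = 0.46 for each of the others. Heat shock genes (median -0.13, 8 of 21 passed as lower), glycolysis genes (median -0.09, 6 of 21) and ganglion cell markers (median -0.08, 3 of 17) lay lower. Adjusted over the list alone, 9, 10 and 3 were lower and 1, 0 and 0 higher. Hsp90aa1 was at -0.38 ± 0.35, Ldha, lactate dehydrogenase A, at -0.43 ± 0.06, and Nefl, the light neurofilament, at -0.33 ± 0.04. Cornea, conjunctiva and iris markers (median 0.21, 3 of 8 passed as higher), myelin genes (median 0.12, 1 of 10) and extracellular matrix genes (median 0.07, 2 of 27 higher and 1 lower) lay higher. Adjusted over the list alone, 8, 1 and 3 were higher and 0, 0 and 1 lower. Krt5, a keratin of surface epithelium, was at 0.32 ± 0.03, Olig1 at 0.26 ± 0.02 and Fn1, fibronectin, at 0.30 ± 0.37. Their preset adjusted p values were 0.0119, 0.0138, 0.0281, 7.13e-05, 0.0281 and 0.0458 in the order given. Genes of 13 families not expected in retina, such as olfactory receptors and pancreatic enzymes, chosen after the data were seen, had a pooled median of 0.09, and 6 of 90 passed as higher and 0 as lower. The medians of the 10 lists kept their sign as deposited, but the myelin and matrix lists no longer passed there, each at an adjusted p of 0.0517. Müller cell and astrocyte markers did not pass (adjusted p 0.191), with a median of -0.03 (0.01 as deposited) and 5 of 21 passed as lower (6 adjusted over the list alone). Glul was at -0.45 ± 0.24, Gfap at -0.03 ± 0.15 and the ganglion cell marker Thy1 at -0.05 ± 0.24. In the model with a dye term, leaving out the array with the 11-week retina in Cy5 gave -0.19 for Hsp90aa1, -0.18 for Ldha, -0.23 for Glul and 0.49 for Fn1. Leaving out that with the 11-week retina in Cy3 gave -0.68 for Ldha, 0.15 for Olig1 and 0.11 for Fn1.

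Over all genes at 11 weeks, the model with a dye term passed 252 as higher and 612 as lower, against 0 without it, where the smallest adjusted p was 0.999 and 367 genes had an unadjusted p under 0.05. As deposited, without centring, 0 genes passed with the dye term. With all probes included, the dye-term model passed 94 as higher and 84 as lower, of which 33 were among the genes passed above. Leaving out either 11-week array reduced the lists past the preset test from 10 to 5.

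**Figure D1:**
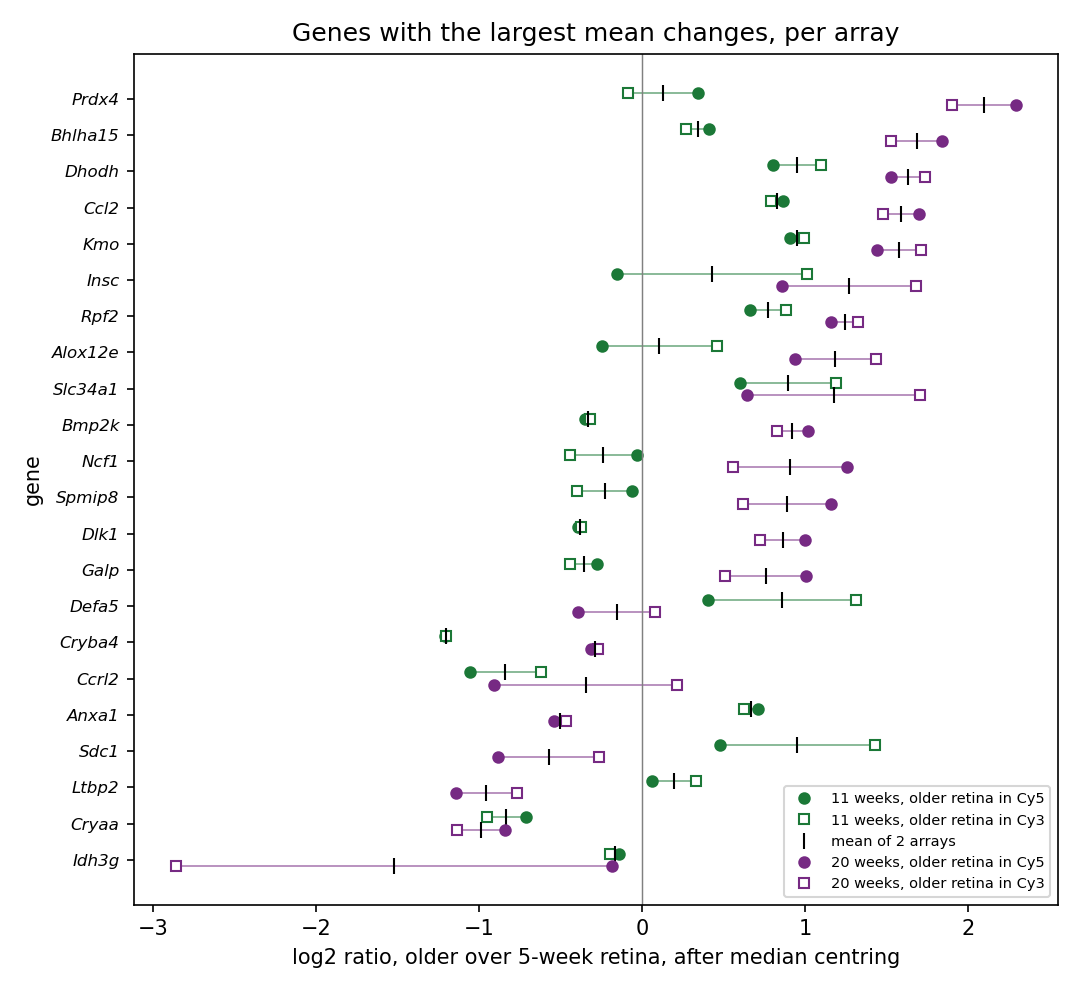
Log2 ratio of the older over the 5-week retina on each array, after median centring (horizontal axis), for the genes with the largest mean changes in any comparison (vertical axis). Filled circles are arrays with the older retina in Cy5, open squares those with it in Cy3, and bars the means of 2 arrays. Prdx4 lay at 2.29 and 1.90 on the 20-week arrays, and Idh3g at -0.18 and -2.86. As deposited, none of the means of 1.0 or more in size changed sign.

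At 20 weeks, the retina differed from 5 weeks by larger values, led by Prdx4, a peroxiredoxin of the endoplasmic reticulum, at 2.10 ± 0.28 (SD, n = 2), a 4.27-fold higher ratio. Its adjusted p was 2.58e-07 with a dye term and 0.182 without. Bhlha15, a transcription factor of secretory cells, was at 1.69 ± 0.22. Dhodh was at 1.63 ± 0.15, Ccl2 at 1.59 ± 0.16, Kmo at 1.58 ± 0.19 and Rpf2 at 1.24 ± 0.12, each above its 11-week value on both arrays. Insc, an adaptor in spindle orientation, was at 1.27 ± 0.58, the lipoxygenase gene Alox12e at 1.19 ± 0.35 and Slc34a1 at 1.18 ± 0.75. Idh3g, a subunit of isocitrate dehydrogenase, was at -1.52 ± 1.89. That value came from 1 of its 2 probes, at -2.92 against -0.12 for the other, and with a dye term it was -0.21 without the array with the 20-week retina in Cy3 and -2.83 without that with it in Cy5. All 10 passed with a dye term and none without.

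The glycolysis, respiratory chain and rod lists had medians below the median gene at 20 weeks, although above 0 as deposited, and each call was lost with an estimated correlation (adjusted p = 0.55). Of 21 glycolysis genes, 12 passed as lower and 0 as higher (16 lower adjusted over the list alone), with a median of -0.26 (0.02 as deposited). Ldha was at -0.70 ± 0.41, Tpi1 at -0.59 ± 0.41, Pkm at -0.58 ± 0.66 and Eno1 at -0.56 ± 0.48. In the model with a dye term, Ldha was at -0.45 without the array with the 20-week retina in Cy3. The adjusted p was 9.10e-06, and adjusted p = 0.55 with an estimated correlation. Of 40 respiratory chain genes, 22 passed as lower and 2 as higher (24 and 4 adjusted over the list alone), with a median of -0.21 (0.06 as deposited). Sdhc was at -0.44 ± 0.03 and Cox7a2 at -0.41 ± 0.02. Camera gave an adjusted p of 6.40e-06, and adjusted p = 0.55 with an estimated correlation. Of 26 rod genes, 12 passed as lower and 0 as higher (13 lower adjusted over the list alone), with a median of -0.19 (0.09 as deposited). Guca1b, a guanylate cyclase activator, was at -0.72 ± 0.16, Rcvrn at -0.66 ± 0.31 and Rbp3, a retinoid-binding protein, at -0.49 ± 0.16. The adjusted p was 8.25e-05, and adjusted p = 0.55 with an estimated correlation.

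Ribosomal protein genes had a median of -0.17 (0.11 as deposited), and 21 of 47 passed as lower and 2 as higher (22 and 2 adjusted over the list alone). Rps10 was at -0.51 ± 0.05. Müller cell and astrocyte markers had a median of -0.27 (0.01 as deposited), and 13 of 21 passed as lower and 2 as higher (14 and 2 adjusted over the list alone). Vim, vimentin, was at -0.45 ± 0.07, Glul, the glutamine synthetase of Müller cells, at -0.45 ± 0.56, and Gfap, a marker of reactive glia, at -0.11 ± 0.17. In the model with a dye term, Glul was at -0.22 without the array with the 20-week retina in Cy3. Ganglion cell markers had a median of -0.16 (0.12 as deposited), and 7 of 17 passed as lower and 1 as higher (8 and 1 adjusted over the list alone). Nrn1 was at -0.58 ± 0.22, Nefh at -0.51 ± 0.22 and Thy1 at -0.31 ± 0.13. Heat shock genes had a median of -0.08 (0.20 as deposited), and 6 of 21 passed as lower and 0 as higher (6 and 0 adjusted over the list alone). Hspa8 was at -0.42 ± 0.36. The preset adjusted p values of these 4 lists were 2.75e-05, 0.00307, 0.0229 and 0.0435, and adjusted p = 0.55 with an estimated correlation for each.

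Immediate early genes lay higher, with a median of 0.13 (0.40 as deposited), and 9 of 22 passed as higher and 1 as lower (9 and 1 adjusted over the list alone). Myc was at 0.93 ± 0.51, Atf3 at 0.60 ± 0.07 and Dusp1 at 0.43 ± 0.05. Skeletal muscle markers had a median of 0.32 (0.59 as deposited), and 5 of 9 passed as higher and 1 as lower (5 and 1 adjusted over the list alone). Mb, myoglobin, was at 0.46 ± 0.11 and Tnni2, a fast-muscle troponin, at 0.40 ± 0.07. Cornea, conjunctiva and iris markers had a median of 0.20 (0.47 as deposited), and 4 of 8 passed as higher and 0 as lower (4 and 0 adjusted over the list alone). Tp63, an epithelial transcription factor, was at 0.49 ± 0.02. The preset adjusted p values were 0.0235, 0.0435 and 0.0334, and adjusted p = 0.55 with an estimated correlation for each. Genes of 13 families not expected in retina had a pooled median of 0.14 at 20 weeks, with the caseins at -0.18, and 37 of 90 passed as higher and 5 as lower. With a dye term in the set test, the muscle and cornea lists no longer passed, at 0.0673 and 0.0562. As deposited, the muscle, cornea and heat shock lists did not pass, at 0.0709, 0.0986 and 0.0575. Lens genes had a median of -0.13 (0.14 as deposited) and an adjusted p of 0.0717. Of these, 6 of 14 passed as lower and 2 as higher (7 and 2 adjusted over the list alone), with Cryaa at -0.99 ± 0.21 and Cryab at -0.64 ± 0.02.

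Over all genes at 20 weeks, the model with a dye term passed 1715 as higher and 1342 as lower (56.1% higher, or 43.9% with the direction turned), against 0 without it, where 888 genes had an unadjusted p under 0.05. As deposited, the median gene lay at 0.29. The dye-term model then passed 132 as higher and 1 as lower (99.2% higher, or 0.8% with the direction turned) and the model without it 94 and 1. With all probes included, the dye-term model passed 1328 as higher and 800 as lower, and 1018 of these were among the genes passed above. Leaving out the array with the 20-week retina in Cy3 reduced the lists past the preset test from 10 to 0.

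**Figure D2:**
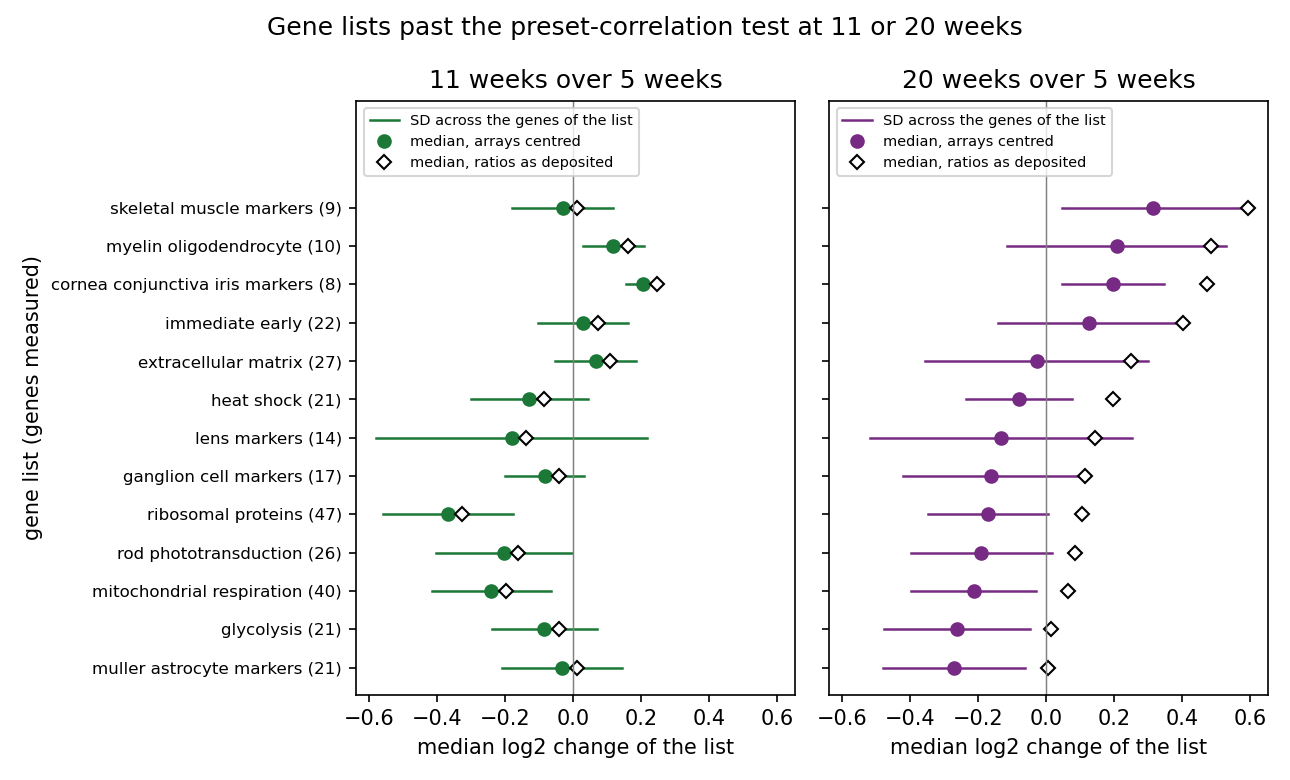
Median log2 change of each gene list that passed the preset set test at 11 or 20 weeks (horizontal axis), with the number of measured genes beside each list name (vertical axis). Filled circles are medians after centring with a line of 1 SD across the genes, and open diamonds are medians as deposited. Ribosomal proteins lay at -0.37 at 11 weeks and -0.17 at 20 weeks after centring, the latter 0.11 as deposited, and all lists below 0 at 20 weeks lay above 0 as deposited.

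The 20-week and 11-week retinas were compared through the 5-week retina, since no array held both. The pairs were hybridised on separate slides, so slide and age cannot be told apart here. Prdx4 was higher at 20 weeks than at 11 by 1.97, with values of 0.34 and -0.09 on the 11-week arrays. Bhlha15 was higher by 1.34, Bmp2k, a kinase gene, by 1.26, Dlk1, a Notch-pathway regulator, by 1.24, Ncf1, an NADPH oxidase subunit, by 1.15, Spmip8 by 1.12 and the neuropeptide gene Galp by 1.12. Lower at 20 weeks were Sdc1, with a difference of -1.53, Anxa1, annexin A1, with -1.17, and Ltbp2, with -1.15. These genes passed with a dye term, and Idh3g, with a difference of -1.35, did not (adjusted p = 0.109). Myc was higher by 1.11, the interferon regulator Irf9 by 0.86 and the metallothionein gene Mt2A by 0.77. Cnp, an oligodendrocyte enzyme, differed by -0.88. Cryba4 was higher at 20 weeks than at 11 by 0.92.

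Ribosomal protein genes lay higher at 20 weeks than at 11, with a median of 0.21 (0.44 as deposited), and 9 of 47 passed as higher and 1 as lower (21 and 3 adjusted over the list alone). Rps24 was at 0.54 and Rpl34 at -0.52. The adjusted p was 0.000563, and adjusted p = 0.84 with an estimated correlation. Glycolysis genes had a median of -0.18 (0.06 as deposited), and 0 of 21 passed in either direction (3 lower adjusted over the list alone). The adjusted p was 0.00953, and adjusted p = 0.90 with an estimated correlation. Skeletal muscle markers had a median of 0.31 (0.55 as deposited), and 3 of 9 passed as higher and 0 as lower (5 and 0 adjusted over the list alone). Camera gave an adjusted p of 0.0312, and adjusted p = 0.84 with an estimated correlation. Of the 31 lists, 3 passed, against 2 without the array with the 20-week retina in Cy5 and 1 without any of the other 3 arrays in turn. Over all genes, the model with a dye term passed 343 as higher and 114 as lower (75.1% higher, or 24.9% with the direction turned), against 0 without it, where 270 genes had an unadjusted p under 0.05. As deposited, the model with a dye term passed 1 gene, as higher. With all probes included it passed 128 as higher and 85 as lower, and 55 of these were among the genes passed above.

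The changes at 11 and 20 weeks had a Pearson correlation of 0.48 and a Spearman correlation of 0.52 across 9653 genes, which are not independent replicates. With 1 array per age the Pearson correlation turned to -0.083 and -0.34 for arrays of opposite dye. It was 0.12 without the array with the 11-week retina in Cy5. The covariance of the mean changes was 0.0168. Both changes share the 5-week retina. Simulated unchanged retinas with array noise only gave r of 0.0009. Simulated pools whose chance differences were as large as the 11-week changes gave r of 0.41 and a covariance of 0.0121. These 2 values follow from the pool variance and array noise put in. The simulated 20-week pool had the same variance, although the measured 20-week changes spread wider (SD across genes 0.23 against 0.16). The arrays were too few to divide the correlation between the shared 5-week pool and changes common to both ages. With a dye term, 180 genes passed as higher at both ages and 295 as lower at both, and 24 passed in opposite directions.

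As deposited, the 2 arrays at 11 weeks correlated at 0.30 across genes and those at 20 weeks at -0.17, and after turning to one direction the values were -0.30 and 0.17. Arrays of different ages with the older retina in the same dye correlated at 0.68 and 0.59. After centring, the dye effect passed for 4403 genes, 2247 toward Cy5 and 2156 toward Cy3, more than any age comparison. As deposited this order did not hold, with 31 genes for the dye effect and 133 for 20 against 5 weeks in the same model. Probes of a gene agreed in part in their measured changes. Across 1683 genes with 2 probes, the probes' changes correlated at 0.29 at 11 weeks and 0.21 at 20 weeks, while 1000 shuffles of the pairing gave at most 0.06 and 0.07. Shuffling breaks anything that the probes of a gene share. The agreement therefore does not tell a change with age from a difference between pools or a bias that depends on signal brightness. The dye effects of the 2 probes correlated at 0.05. At 20 weeks, 109 genes had probes that passed in opposite directions, and at 11 weeks 7 had.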

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

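The bound of 1 on the log2 scale used here and the use of the model with a dye term for this contrast were chosen after the results were seen. Over all 9653 genes, 457 passed the test of this difference with a dye term. Of 133 genes named for 20 against 11 weeks, mostly by the size of this same difference, 50 passed it with a dye term, and 0 without it. The 11 whose difference was at least 1 are given here, each because its change from 5 weeks differed between the ages.

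Prdx4 differed by 1.97 (0.13 at 11 weeks, 2.10 at 20 weeks, adjusted p 1.38e-05). Bhlha15 differed by 1.34 (0.34 and 1.69, adjusted p 0.000258). Sdc1 differed by -1.53 and turned from 0.95 to -0.57. Anxa1 differed by -1.17 and turned from 0.67 to -0.50. Ltbp2 differed by -1.15, from 0.20 to -0.96. The other 6 lay below 0 at 11 weeks and above 0 at 20 weeks. Bmp2k differed by 1.26, Dlk1 by 1.24, Ncf1 by 1.15, Spmip8 by 1.12, Galp by 1.12 and Myc by 1.11. As deposited, without centring, 1 gene of all tested passed this difference with a dye term.

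Calls were also made among probes that the comparisons left out. Of 9650 probes with no listed gene that had values enough for the test, 1110 passed at 20 weeks with a dye term, 692 as higher and 418 as lower. Control spots are not separable from gene probes among them, so this count was not compared with a control level.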

How the results depend on the processing

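All probes, the dye term with another choice, and the dye term with an estimated correlation were added after seeing the data. The cause of each change below was not tested, unless stated. The count of 0 genes became 864, 3057 and 457 with a dye term (11 against 5, 20 against 5, 20 against 11 weeks), and 23, 206 and 102 genes changed at least 1.5-fold in one direction on both arrays, with no test. At 20 against 5 weeks it became 95 as deposited and 5 without the 50% of genes with smaller ratios, and 0 to 5 with 1 array left out, where a lone array is assumed to vary like the others. At 20 against 11 weeks it became 1 as deposited. All other planned settings and all probes gave 0. With the dye term, counts as deposited were 0, 133 and 1. A 1.5-fold threshold left 23, 208 and 177, as fewer genes can pass. With all probes, 178 passed at 11 weeks (52.8% higher, against 29.2%, or 47.2% against 70.8% with the direction turned). At 20 weeks 2128 passed (62.4% higher, against 56.1%, or 37.6% against 43.9% with the direction turned), and 213 at 20 against 11 weeks. Of these, 33, 1018 and 55 were among the 864, 3057 and 457 genes passed with named probes, so most of those calls were lost. The dye effect passed for 31 genes as deposited, against 4403. Without each array in turn, the dye-term model has no test.

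The correlation of the age changes was -0.083 and -0.34 from arrays of opposite dye and 0.68 and 0.59 from arrays of the same dye, and 0.12 to 0.43 with 1 array left out. Lists past the preset test numbered 10, 10 and 3. They numbered 0 in each comparison with an estimated correlation, with it and a dye term, and with fry tested in one direction. An estimated correlation leaves camera 2 residual degrees of freedom, or 1 with a dye term. The 0 counts with it were thus nearly fixed by the number of arrays. The mixed test of fry, which asks for change in either direction, passed 2, 10 and 1. As deposited, 8, 8 and 3 passed, and 5 of the 23 calls were lost. With a dye term, 6 passed at 20 against 11 weeks. With 1 array left out, 5 to 10, 0 to 11 and 1 to 2 passed. Of 4341 values of named genes under alternatives, 112 had the other direction. The dye term, robust moderation, all probes and leaving out genes keep a gene's mean change, so the direction could not turn there. An array left out also keeps the change of the comparison that does not use it. As deposited, 18 of the named values turned, and with 1 array left out 9 to 29 turned. With a dye term, 254 of 399 named values passed. Signal over background was not used here, so its limit on each gene is unknown.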

Other observations

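The tests on a single array, on lens tissue, on the size of the crystallin changes and on sex make-up were chosen after the results were seen. The test on genes not expected in retina was written before its median was computed, although values of a few members had been seen among the largest changes. Counts of passing genes are from the model with a dye term, and none of these genes passed without it over all genes. Of all 9653 genes, the model with a dye term passed 1715 as higher and 1342 as lower at 20 weeks. At 11 weeks it passed 252 and 612. The counts of a list are to be read against these shares, and several lie near them. All list medians below 0 at 20 weeks lay above 0 as deposited.

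Of 22 complement and antigen presentation genes, 9 passed as higher and 2 as lower at 20 weeks (10 and 3 adjusted over the list alone), with a median of 0.18 and RT1-Ba, a class II gene, at 0.50. At 11 weeks 3 passed as higher, with Serping1 at 0.34. Of 22 microglia and leukocyte genes, 5 were higher and 1 lower at 20 weeks, with Tyrobp at 0.43 and Ctss at -0.46. Of 17 interferon genes, 3 were higher and 1 lower, with Irf9 at 0.62. Of 16 retinal stress genes, 4 were higher and 1 lower, with Fgf2 at 0.31 and Cebpd at -0.53. Among 17 clock genes, 2 were higher and 4 lower at 20 weeks, with Per2 at 0.49 (0.26 without the array with the 20-week retina in Cy5) and Clock at -0.32, and none passed at 11 weeks. The hour of dissection is not given in the sources used here. None of these lists passed camera at either age, with preset adjusted p at 20 weeks of 0.188, 0.373, 0.746, 0.412 and 0.835.

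Other neuronal lists did not pass camera either. At 20 weeks, medians were 0.04 for 10 cone genes (3 higher, Opn1mw at 0.39), -0.01 for 11 bipolar genes (2 lower, Pcp2 at -0.38), -0.02 for 18 amacrine and horizontal genes (2 higher, 3 lower), -0.09 for 37 synapse genes (4 higher, 11 lower, Syp at -0.45) and -0.02 for 31 neuronal development genes (4 higher, 8 lower, Stmn1 at -0.59). Neighbouring tissues gave 0.04 for 13 pigment epithelium and choroid genes (2 higher, 1 lower, Tyr at 0.77), 0.14 for 5 blood genes (2 higher), -0.05 for 17 vessel genes (2 higher, 3 lower, Rgs5 at -0.68), 0.21 for 10 myelin genes (4 higher, 1 lower) and -0.03 for 27 matrix genes (5 higher, 6 lower, Sparc at -0.75). The rest gave 0.05 for 28 cell cycle genes (5 higher, 3 lower), 0.04 for 26 apoptosis genes (5 higher, 2 lower), -0.03 for 38 antioxidant genes (7 higher, 11 lower), -0.04 for 25 lipid synthesis genes (2 higher, 5 lower) and -0.03 for 21 growth and thyroid hormone genes (3 higher, 3 lower). Adjusted over the list alone, the counts were 7 higher and 4 lower for cell cycle, 8 and 14 for antioxidant, 5 and 11 for synapse, 6 and 6 for matrix and 1 and 1 for pigment epithelium genes, and, apart from the complement list, unchanged for the others at 20 weeks. Median, mean and camera direction differed in sign for antioxidant, clock and hormone genes at 20 weeks and for cone genes at 11 weeks. For 20 against 11 weeks they differed for amacrine and horizontal, antioxidant, clock, heat shock, interferon, myelin, neuronal development and pigment epithelium genes.

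Ribosomal, respiratory chain and rod genes, all abundant in retina, lay below the median gene at both ages (above 0 as deposited at 20 weeks), which a bias that depends on signal brightness could produce, with genes dim in retina then above the median gene. A set of 90 genes of 13 families not expected in retina, such as olfactory receptors and pancreatic enzymes, had a pooled median of 0.139 at 20 weeks (95% interval 0.0815 to 0.204) and 0.086 at 11 weeks (0.0645 to 0.108), as that explanation needs, although the caseins were at -0.18 at 20 weeks and the seminal and salivary secretions at -0.03 at 11 weeks. None of them is in the other lists. At 20 weeks 37 of the 90 passed as higher, against 1715 of 9653 over all genes. A bias that followed the dye alike on both arrays of a pair would cancel in their mean. After turning to one direction, ribosomal medians were -0.29 and -0.44 at 11 weeks, older retina in Cy5 and in Cy3. At 20 weeks they were -0.07 and -0.23. Respiratory chain and rod medians were also below 0 on each array. For these lists the values argue against such a dye bias alone. A brightness bias that followed the older retina or differed between slides stays open, and it was not tested on single lists or genes. The other lists past the preset test at either age are therefore open to it too, and so are single named genes. Among these lists are glycolysis, immediate early, muscle and cornea. A single aberrant array is argued against for the sign of the ribosomal median. It was below 0 on 4 of 4 arrays once the dye effect estimated on the other pair was taken out. The size still differed between arrays. At 20 weeks the rod median, so treated, was -0.26 with the older retina in Cy3 and -0.13 in Cy5, and -0.45 and -0.04 with the dye effect left in. A change with age in these genes stays open, untested apart from the bias.

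The 9 crystallin genes had medians of -0.46 at 11 weeks and -0.29 at 20 weeks, and 7 and 5 passed as lower, although the lens list did not pass at 20 weeks (adjusted p 0.0717). Lens tissue in the 5-week pool could produce this. The 5 other lens genes had medians of 0.0095 at 11 weeks and 0.10 at 20 weeks, but whether their probes lie above background is unknown, so lens tissue and a change with age cannot be told apart. Of 10000 medians of 9 genes drawn from 87 ribosomal and respiratory chain genes, 0.72% lay below the crystallin median at 11 weeks and 4.32% at 20 weeks. The crystallins thus lay low among these draws, but they were set apart after their changes were seen, so their place was partly selected. How bright the crystallin probes are is unknown, which leaves a brightness bias open.

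Uty, a Y-linked gene singled out after its values were seen, was at -1.01 at 20 weeks (adjusted p 2.14e-05 with a dye term) and -0.19 at 11 weeks. A lower share of males in the 20-week pool could produce this. The sex of the animals is not given in the sources used here. The X-linked Eif2s3 was at 0.166 and Ddx3x at -0.06 at 20 weeks, neither past the threshold, and the only other Y-linked gene measured, Tspy1, was at -0.18. Tspy1 is mainly a testis gene, so sex make-up and a change in Uty itself cannot be told apart.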
